A study of Drosophila melanogaster with 4 samples.

How the data were processed

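Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos aged 16 to 24 h. The target was cap'n collar (CNC), a basic leucine zipper transcription factor of the family that includes vertebrate Nrf2. The series holds 4 libraries: 2 from CNC immunoprecipitation with a rabbit polyclonal antibody and 2 from input DNA, which is sheared chromatin that was not immunoprecipitated. Per the labels' protocols, eggs were laid over 8 h and embryos were fixed in 1.8% formaldehyde for 15 min. The labels do not say whether the 2 replicates of a group came from separate collections of embryos.

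The data analysed here are 1 peak list for the whole series. The submitters' processing notes name CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA, MACS2 and the genome build BDGP5. The list gives MACS as its source and FlyBase release 5 as its build, per the file headers. For each peak it holds the chromosome arm, start and end, and a peak score assigned by the authors. The statistic behind the authors' score and its scale, the peak threshold, and whether the libraries were pooled before calling are not given in the sources used here. The score is used only within this list. Ranks, selections and Spearman's rho do not depend on its scale, whereas Pearson's r and differences in log2 score do. Enrichment per peak, library depth and signal in each replicate were not analysed here. No spread between replicates, confidence interval of a peak or test of immunoprecipitation against input can be given, and every test below describes how peaks are arranged within the list. The read depth is unknown.

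Coordinates are 1-based on release 5 as deposited. The gene table at hand was for release 6 of the genome, so no peak was assigned to a gene, exon, intron or promoter. For the same reason the planned tests of transcription start sites, genomic annotation, 26 gene lists and the antioxidant response element were not run. Peaks are named by position, by a rule fixed before the data were examined: the 20 peaks with the highest score, the strongest peak of each of the 6 arms (2L, 2R, 3L, 3R, 4 and X), and the 5 widest peaks. Windows and multi-peak regions named below, and the full sets of peaks on chromosome 4 and on Uextra, were chosen after their values were seen. Uextra is a collection of sequence not placed on an arm, and its peaks were left out of the comparisons between arms and of spacing but are part of the correlation of score with width.

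The position of a peak was its midpoint, since no summit is listed. Score and width were compared across peaks by Spearman's rho and Pearson's r with 100000 permutations. Scores on X were compared with those on the 4 large autosomal arms by the difference in median log2 score, with 100000 permutations and a 95% interval from 2000 resamplings of 1-Mb bins. The share of peaks on each arm was compared with the arm's share of the summed spans by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 6 arms. An arm's span ran from its first to its last listed peak, because neither the list nor the labels give arm lengths. Clopper-Pearson intervals of these shares cover counting error only. As peaks proved to be clustered, a permutation test with 1-Mb bins as the units was added after seeing the data, with adjustment over the 5 large arms, and both tests were repeated with spans from coordinate 1. Distances between the midpoints of neighbouring peaks were compared with 1000 uniform placements of the same number of peaks within the span of each arm. The smallest two-sided p that these placements can give is 0.0020, and the smallest that the permutations can give is 1.0e-05.

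Alternatives fixed before the data were examined used the 50% or 25% of peaks with the highest scores, merged peaks whose edges were under 200 bp apart, and changed the statistic, the measure or the placement. All computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The procedures were tested on simulated lists of the same size, 50 for each case with 200 permutations or placements. Clustering was detected in 50 of 50 clustered lists and in 3 of 50 lists with no effect. A shift of 0.25 in log2 score on X was detected in 50 of 50 lists with a median estimate of 0.25, and with no effect the test called 5 of 50 lists. The shift was put on peaks already listed, with no peak threshold applied. This rate therefore does not give the power of the X test in the real list. With no enrichment of 2R the binomial test called 2R in 5 of 50 lists with no effect and in 14 of 50 clustered lists, and the test on 1-Mb bins called it in 5 of 50 and 3 of 50. The clustered lists put part of the peaks close to others that were placed uniformly. They lack the differences between megabases and the long groups of the real list. These rates therefore do not give the false calls of either arm test in the real list.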

Results

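CNC binding was profiled in embryos aged 16 to 24 h, late in embryogenesis, by comparing CNC immunoprecipitate (2 libraries) with input DNA (2 libraries). CNC is the fly counterpart of vertebrate Nrf2. A long isoform activates detoxification and antioxidant genes, and another acts in patterning the embryonic head. The design asks where in the genome CNC occupies chromatin at this stage. The peak list names 4758 peaks that together cover 2.99 Mb. Merging peaks with edges under 200 bp apart left 3945, and merging those under 1000 bp apart left 2731. The large arms carried nearly all of them, with 1249 on 3R, 1032 on 2R, 874 on 3L, 801 on 2L and 789 on X. Chromosome 4 carried 7 peaks and the unplaced sequence Uextra 6. The list gives 1 score per peak for the whole series, so each score below is the authors' single value, without replicates.

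Most peaks were narrow with low scores, and a small set was broad with high scores. The median peak was 382 bp wide with a score of 12.5, and the middle 50% of scores ran from 10.0 to 17.6. Scores reached 318.19, and 55 peaks scored 100 or more. Of these, 15 lay on 3R, 14 on 2R, 11 on X, 10 on 2L and 5 on 3L. Their median width was 3652 bp, against 378 bp for the other peaks, and the narrowest of them spanned 1700 bp. Peaks of 2000 bp or more made up 4.52% of the list (215 peaks) and 23.1% of the covered bases. The narrowest listed width was 201 bp, which 115 peaks shared.

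The highest-scoring peak lay on 2R from 5578417 to 5581293. It scored 318.19, against 232.21 for the next peak, it was 2877 bp wide, and it had no other peak within 5 kb. Another high-scoring and compact site, 1700 bp wide with a score of 205.79, lay on the same arm from 5875816 to 5877515. The other 2R sites among the 20 strongest started at 9424941, 9844577, 3361885 and 14740950, with scores of 189.74, 182.73, 178.71 and 158.38. On 3R the strongest site ran from 12899839 to 12906369 with a score of 232.21 and a width of 6531 bp. The next on 3R started at 19012893 (score 218.91), 1614112 (score 200.32), 14739062 (score 173.48), 19555418 (score 164.77) and 24977185 (score 153.54). The arm 2L held 3 of the 20 strongest, led by a site from 9787912 to 9793243 with a score of 224.97. X held 5, led by a site of 2301 bp from 12628389 to 12630689 with a score of 221.61. The remaining X sites started at 8004810, 11657649, 11017822 and 19208487 and scored from 150.22 to 167.86. No site of 3L or of chromosome 4 was among the 20. The strongest peak of 3L, from 1333294 to 1337370, scored 126.14 and ranked 29 in the list, and the strongest of chromosome 4, from 1000373 to 1001010, scored 23.27 and ranked 699. Of the 20 strongest sites, 19 had at least 1 other peak within 5 kb.

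The widest continuous peak covered 11392 bp of 2L, from 8688269 to 8699660, with a score of 167.57 and rank 13 by score. The next widest covered 9089 bp of 2R, from 14286874 to 14295962, and scored 97.79. The other 3 of the 5 widest were also among the 20 strongest: 6974 bp on 3R from 1614112, 6919 bp on 2L from 16525261 to 16532179, and the 6531 bp of the strongest 3R site.

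Broader peaks scored higher, and both values come from the same peak call on the same reads, so they are not independent measurements. Among the 25% of peaks with the smallest widths (201 to 260 bp) the median score was 9.86, and among the widest 25% (676 to 11392 bp) it was 23.9. Across the 4758 peaks score and width were correlated, with Spearman's rho of 0.74 and Pearson's r of 0.79 (permutation p = 1.0e-05 for both, the smallest the permutations can give, and peaks are not independent replicates). Within the single large arms rho ranged from 0.71 on X to 0.76 on 2L. On chromosome 4, where the 7 peaks were too few for the same treatment, scores ran from 8.52 to 23.27.

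**Figure D1:**
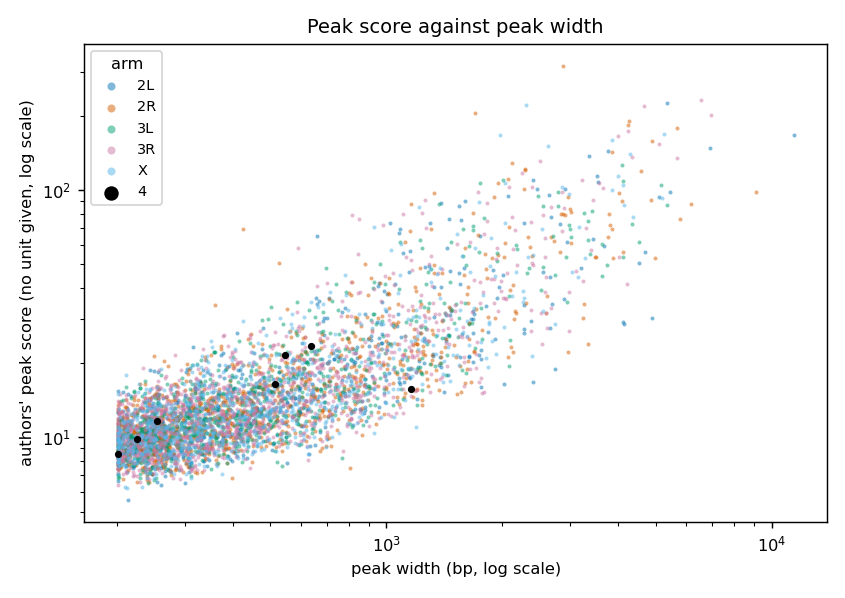
Authors' peak score (vertical, log scale, no unit given) against peak width in bp (horizontal, log scale) for each peak on the 6 arms, 1 point per peak and 1 colour per arm. Score rises with width (Spearman's rho 0.74), and the 7 peaks of chromosome 4, in black, lie between scores of 8.52 and 23.27.

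The X chromosome and the autosomes were compared for the strength of their sites. The median score was 12.3 over 789 peaks on X and 12.5 over 3956 peaks on 2L, 2R, 3L and 3R. The difference of -0.02 in median log2 score (X minus autosomes) did not pass the permutation test (p = 0.40). Resampling of 1-Mb bins gave a 95% interval from -0.10 to 0.04. Weaker sites on X could fall below the peak threshold, which is not given, so the medians of listed peaks cannot show equal strength. The sex ratio of the embryos and the copy number of X are not given either.

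The arms differed in how densely peaks lay along them. The arm 2R carried 53.7 peaks per Mb of its span and 3R 45.0, against 38.4 on 3L, 37.5 on X and 37.0 on 2L, and chromosome 4 carried 7.68 per Mb. Relative to their shares of the summed span, 2R held 1.28 times as many peaks (21.7% of peaks, 95% Clopper-Pearson interval 20.6 to 22.9%, against 16.9% of the span), and chromosome 4 held 0.18 times as many (7 peaks against 38.2 for an even spread). In exact binomial tests with Benjamini-Hochberg adjustment, 2R (adjusted p = 1.3e-16) and 3R (1.07 times, adjusted p = 0.0041) were above an even spread. In the same exact tests chromosome 4 (adjusted p = 4.9e-09), 2L (0.88 times, adjusted p = 0.00013), X (0.89 times, adjusted p = 0.00059) and 3L (0.92 times, adjusted p = 0.0041) were below it.

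These binomial values treat each peak as independent, which clustered peaks are not. With 1-Mb bins as the units, 2R held 53.9 ± 20.9 peaks per bin (SD over 19 bins) and the other large arms 40.0 ± 17.9 (SD over 91 bins), with an adjusted permutation p of 0.016. The ratio of these means was 1.35. Without the densest 2R bin, which held 101 peaks, the ratio was 1.28 and the adjusted permutation p 0.080. Only 2R lost a bin, which lowers its mean by construction, so this cannot show that 1 bin drives the excess. With covered bases per bin in place of peaks the ratio was 1.48 (adjusted permutation p = 0.0042). Covered bases were tested only in bins from the first peak, and not from coordinate 1 or without the densest 2R bin. The span matters for 2R, whose first peak starts at 1869726, against 173145 or less on each other arm. Counted from coordinate 1, 2R carried 49.0 peaks per Mb and 1.19 times its even share (exact binomial test, adjusted p = 3.3e-09), and its ratio of bin means was 1.23 and did not pass (adjusted permutation p = 0.29). Only the start of each span was moved, and its end stayed at the last peak. Spans from the first peak leave out more sequence of 2R than of any other arm, which raises the density of 2R. Spans from coordinate 1 lower 2R more than the other arms and still leave out sequence beyond the last peaks. Neither choice is neutral, and whether 2R passes the test in bins depends on it. The other large arms did not pass the test in bins, with adjusted permutation p of 0.26 for 2L and X and 0.37 for 3L and 3R. Chromosome 4 is shorter than a bin by its span and could not be included, so no test that allows for clustering was run on it.

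**Figure D2:**
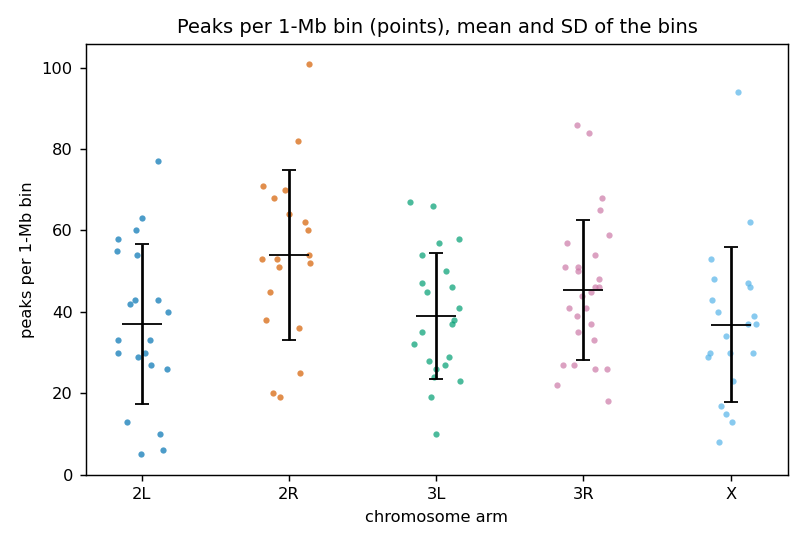
Number of peaks in each 1-Mb bin (points) on the 5 large arms, with the mean and SD of the bins in black and bins counted from the first peak of each arm. Bins on 2R average 53.9 peaks and reach 101, and the bins of all arms overlap widely.

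Along each arm the sites were unevenly spread. The densest megabase was 2R from 3 to 4 Mb with 99 peaks, followed by 2R from 5 to 6 Mb with 96, 3R from 5 to 6 Mb with 86, 3R from 12 to 13 Mb with 84, X from 1 to 2 Mb with 82 and 2L from 0 to 1 Mb with 77. At the other end, 2L from 17 to 18 Mb held 5 peaks, and 2L from 11 to 12 Mb and X from 20 to 21 Mb held 9 each. The megabases of 2R from 1 to 2 Mb and from 21 to 22 Mb, which hold the ends of its span, had 6 and 3 peaks.

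**Figure D3:**
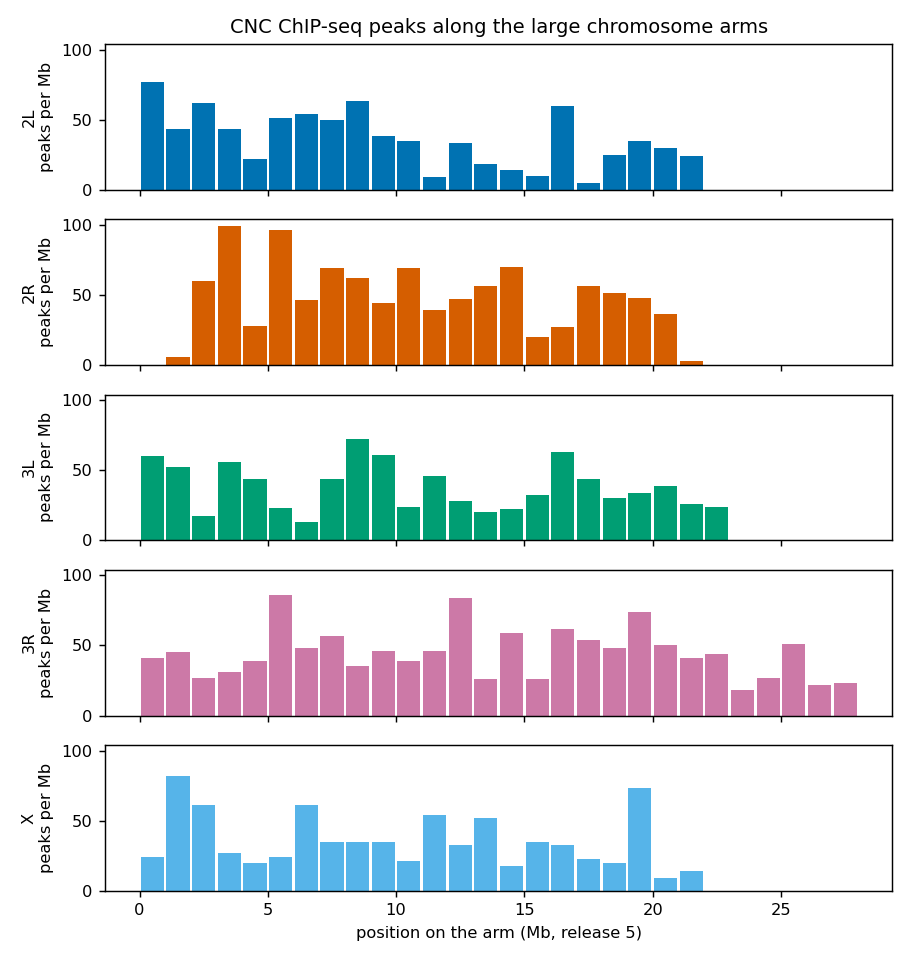
Number of peaks (vertical) in each megabase (horizontal, position in Mb on release 5) of 2L, 2R, 3L, 3R and X. The tallest bars are 2R from 3 to 4 Mb with 99 peaks and from 5 to 6 Mb with 96.

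CNC peaks lay in groups. The median distance between neighbouring peak midpoints was 2510 bp, or 0.15 times the 16.2 kb of uniform placements, whose lowest median was 15.4 kb (permutation p = 0.0020, the smallest that 1000 placements can give). Neighbours under 5 kb apart made up 60.4% of neighbouring pairs against 19.4% in placements (permutation p = 0.0020). The ratio of median distances rose to 0.26 and 0.49 with the 50% and 25% of peaks of highest score, and to 0.23 and 0.45 with peaks under 200 and under 1000 bp apart merged, and stayed below 1 in each (permutation p = 0.0020). Keeping fewer peaks of a grouped list can raise the ratio whatever their score, and merging removes short distances by construction. The rise therefore does not show that stronger peaks are less grouped. The grouping was present on each large arm, where the ratio to placements ran from 0.14 on X and 3R to 0.19 on 2R. The 7 peaks of chromosome 4 were too few to show grouping or its lack, with a median distance of 143 kb inside the 13.2 to 171 kb of placements (permutation p = 0.054). When peaks with edges under 5 kb apart were joined, 82.0% of the 4752 peaks on the 6 arms fell into 962 multi-peak regions, and 855 peaks stood alone.

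The largest groups were long stretches of closely spaced peaks. On 3R, 40 peaks followed one another from 12031119 to 12088837, a stretch of 57.7 kb in which no score exceeded 49.59. On 2R, 28 peaks lay from 7059913 to 7096946 (37.0 kb), with a highest score of 142.91. Next were 21 peaks on 3L from 8666453 to 8699324 and 18 peaks on 3R from 21110256 to 21138016. In windows of 100 kb, 3R from 12.0 to 12.1 Mb held 50 peaks over 28.3 kb of covered sequence, and 2R from 7.0 to 7.1 Mb held 28 peaks over 30.2 kb. The fullest window of any uniform placement held 20 peaks, a number that 15 observed windows exceeded. After peaks with edges under 1000 bp apart were merged, 1 window, that of 3R with 15 regions, exceeded the 13 of the fullest placement. No peak was listed in 330 of the 1139 windows, against 14 to 40 empty windows in the placements.

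**Figure D4:**
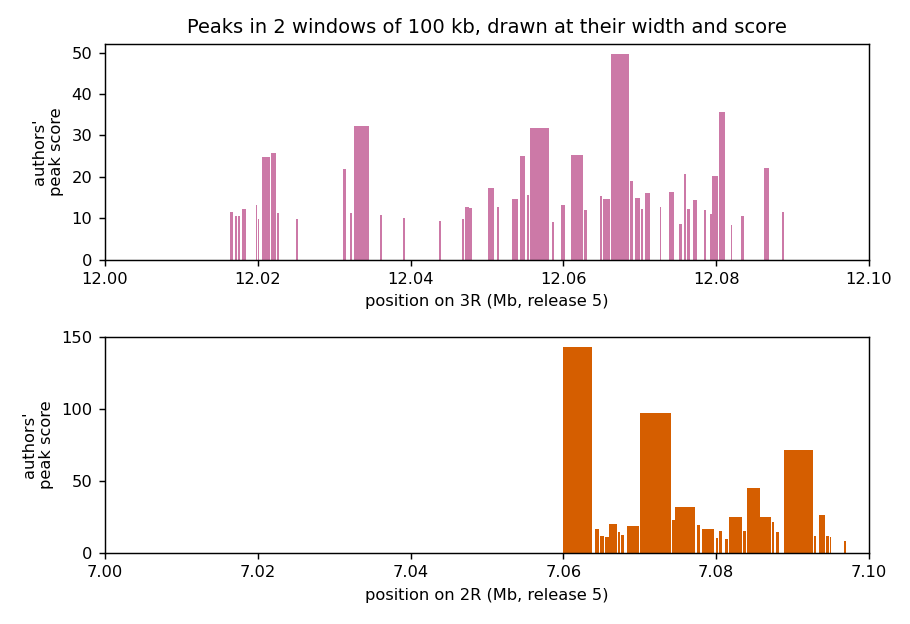
Peaks in the windows 3R from 12.0 to 12.1 Mb (top) and 2R from 7.0 to 7.1 Mb (bottom), each drawn at its width along the arm (horizontal, Mb on release 5) and at the authors' score (vertical, no unit given, separate scales). The 3R window holds 50 peaks with scores up to 49.59, and the 2R window 28 peaks with scores up to 142.91.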

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

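Outside the comparisons between arms and of spacing, 6 peaks lay on Uextra, sequence not placed on a chromosome arm. They are listed here because those comparisons leave them out, and no expected number was available to set them against. Of the 6, 5 scored above the median of the whole list, and their median was 18.9 against 12.5. The strongest ran from 7039430 to 7039700 with a score of 32.04, and the next from 19603911 to 19604123 with a score of 27.68. No explanation was tested for them.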

How the results depend on the processing

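Score against width kept its direction and stayed past the threshold under the 4 alternatives run. X against autosomes did not pass the test under any of its 5, and peak grouping stayed past the threshold under its 6. For X, taking the 50% or 25% of peaks of highest score selects by the very score compared, which can hide a shift. Leaving out the widest peaks selects by a trait correlated with score. These alternatives therefore do not show equal scores. Merging peaks under 1000 bp apart, an alternative chosen after seeing the data, left 2731 peaks of 4758. The arm counts were less stable, and the values that no longer passed follow. As ratios of observed peaks to an even spread, with the 25% of peaks of highest score these were 0.89 for 2L, 0.91 for 3L and 1.06 for 3R, where fewer peaks were tested. With peaks under 200 bp apart merged they were 0.94 for 3L and 1.04 for 3R. The values in bins are on another scale, the mean bin of an arm over the mean bin of the other large arms. With covered bases per 1-Mb bin they were 0.90 for 2L, 0.85 for 3L, 1.06 for 3R and 0.79 for X. With peaks per 1-Mb bin, added later, they were 0.85 for 2L, 0.90 for 3L, 1.10 for 3R and 0.85 for X, where the units are fewer. For 2R this ratio of bin means was 1.35 with all bins, which passed. Those bins were counted from the first peak, a span that favours 2R. Without the densest bin of 2R, while the other arms kept theirs, it was 1.28 and did not pass (also added later). With bins counted from coordinate 1, also added later, no large arm passed, at 0.87 for 2L, 1.23 for 2R, 0.91 for 3L, 1.12 for 3R and 0.87 for X. The sequence before the first 2R peak then counts for 2R, with no peak in its first megabase and 6 from 1 to 2 Mb. The spans still ended at the last peak of each arm. The binomial calls stayed past the threshold with spans from coordinate 1. Otherwise the cause was not tested. The low count on chromosome 4 stayed past the threshold with the 50% and 25% of peaks of highest score and after merging under 200 bp. It could not be tested in bins. Joined under 5 kb, 82.0% of the peaks on the 6 arms fell into multi-peak regions, whereas the 7 of chromosome 4 each stood alone. Its ratio of 0.18 therefore counts peaks and not such regions, and no test by region was run. Assembled arm lengths were not used here, so that alternative was not run, nor were those of the start site, annotation, gene list and motif tests. No paired analysis was possible because the single peak list holds no value per replicate, and for the same reason no replicate could be left out. Read depth is unknown.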

Other observations

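Of the tests in this part, the one that keeps the number of peaks per megabase was planned, the prediction for the 3R window was written before its result was seen, and the others were chosen after the result was seen. Taken peak by peak, no difference in score was detected between peaks that stood alone and peaks in groups. The 855 peaks with no other peak within 5 kb had a median score of 12.3 and a median width of 372 bp. The 3897 peaks in groups had a median score of 12.6 and a median width of 384 bp, a difference of 0.03 in median log2 score (permutation p = 0.29). Of the 55 peaks scoring 100 or more, 5 stood alone and 50 lay in groups (Fisher's exact test, two-sided p = 0.11). The highest-scoring peak of the list, on 2R from 5578417 to 5581293, was among those that stood alone. The 7 sites of chromosome 4 each stood alone, at starts of 89342, 328395, 378736, 436200, 578504, 856229 and 1000373.

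The grouping of peaks could come from 1 enriched region being listed as several peaks under 1000 bp apart, or from megabases that differ in peak density. The tables argue against each of these as the whole cause. After peaks with edges under 1000 bp apart were merged, the median distance between the 2725 remaining regions was still 0.45 times that of uniform placements. Against placements that keep the number of peaks in each 1-Mb bin, the ratio was 0.17. Wider merging gave 0.70 (under 5000 bp, 1817 regions) and 0.98 (under 20000 bp, 1060 regions), but it removes short distances by its construction, so broad regions split over longer gaps stay open. The design holds 1 stage and 1 target, so no biological explanation was tested. Uneven mappability and uneven chromatin accessibility along the arms were not tested and stay open.

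The window on 3R from 12.0 to 12.1 Mb, with 50 peaks, may hold a dense array of separate sites, or its number may come from splitting into peaks under 1000 bp apart or from a general high enrichment that lifts weak sites past the threshold. Merging under 1000 bp left 15 regions, above the 13 of the fullest window in 1000 uniform placements. Such splitting alone thus does not bring the window within those placements. They are a weak standard, since merged regions lay closer than uniform across the list (0.45 times). The lead over any other observed window fell from 50 peaks against 28 to 15 regions against 12. How much of the excess comes from such splitting stays open. Merging under 5000 bp left 2 regions, 1 of them holding 40 of the peaks, so 1 broad region with longer gaps stays open. A general enrichment cannot be told apart here. The median score in the window was 12.745, inside the 11.2 to 14.6 spanned by 95% of 10000 draws of as many 3R peaks, but added weak peaks would lower a raised median, and coverage in the input was not analysed here.

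A hypothesis that neighbouring peaks carry similar scores was tested in 4 classes of distance between their edges, with 100000 permutations within arms, adjustment over the 4 and approximate 95% intervals (Fisher transformation). Scores were ranked within each whole arm and divided by its number of peaks. Here rho is Pearson's correlation of these ranks between neighbours, without ranking again within a class. The intervals treat pairs as independent, although neighbouring pairs can share a peak. For the 813 pairs under 200 bp apart this rho was 0.0987 (interval 0.03 to 0.17, adjusted permutation p = 0.019), a weak similarity. Similar scores were not seen at longer distances. For 1214 pairs from 200 to 1000 bp apart rho was 0.0227 (interval -0.03 to 0.08, adjusted permutation p = 0.57). For 908 pairs from 1000 to 5000 bp apart it was -0.0801 (interval -0.14 to -0.02, adjusted permutation p = 0.032). This class passed the threshold in the opposite direction, a weak dissimilarity. For 1805 pairs over 5000 bp apart rho was -0.0036 (interval -0.05 to 0.04, adjusted permutation p = 0.88).

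Scores thinned out towards the low end of the list: 33 peaks scored under 7 and the lowest was 5.55, while 529 scored from 10 to 11, the fullest unit interval.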
